A study of Homo sapiens with 4 samples.

How the data were processed

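RNA from 4 cultures was hybridised to Illumina bead arrays, 1 array per group, so no group had a replicate. Per the labels' protocols, cells grown in DMEM with serum were taken at partial confluence, total RNA was extracted with a miRVANA kit, and biotin-labelled cRNA was made for the arrays. Groups followed the titles and the genotype labels. For Ls-Parental the title and source name were used, since its cell line entry names LvM3b.

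The deposited non-normalized table holds, per the file headers, a signal and a Detection column for each array. The signal is a probe intensity on a linear scale that the authors deposited without normalization between arrays. Detection is a score from 0 to 1 in the deposited table that is high for bright probes, and 1 minus it was used as the detection p. A second table of processed intensity values deposited by the authors equals the first times 1 factor per array (1.0 for the LvM3b control, 1.03 for miR-483, 1.11 for miR-551a and 1.09 for Ls-Parental), which sets each median to 115.4; this was found from the values, on a linear scale with no centring. The software behind either table is not given in the sources used here. Median deposited signals were 115.4, 112.5, 103.6 and 106.0, and the lowest detected signals were 178.2, 159.8, 146.5 and 148.9, in the same order. The files hold no bead numbers or bead standard errors, so no interval within an array was computed.

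From the deposited signals, limma 3.58.1 in R 4.3.3 computed normexp background correction from the detection p-values with an offset of 16, quantile normalization of the 4 arrays together, and log2 values (neqc). A probe was detected at a detection p under 0.01. Probe names came from the platform annotation supplied with the series, updated by gene number through the RefSeq table of GRCh38.p14: 27578 probes had 1 gene, 13 had several and 21212 had none, and 27541 matched. Probes with several genes or none were not counted as genes, and 121 probes of the Y chromosome or XIST were left out. Each of the 18589 genes was read from its brightest probe by mean level over the 4 arrays. No genomic positions are printed, since the files name no build.

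Comparisons were miR-483 over control, miR-551a over control and LvM3b control over Ls-Parental, as log2 differences of genes detected on at least 1 of the 2 arrays, counted at 2-fold. With 1 array per group there is no test. Where a gene was not detected on the dimmer array, the bound set the bright array's level against the higher of the lowest level among detected probes on the dim array and the gene's own level there. Each gene list was described by its median and by the percentile of that median among 10000 random lists of the same size, each member replaced by 1 of 100 genes nearest in mean level; lists with fewer than 3 detected members got none. For CKB the number of the 500 genes nearest in level that differed as far was counted. The similarity of the microRNA comparisons was set beside 1000 simulations of unchanged arrays that share 1 control, with noise matched to the observed spread. The control's noise was assumed no larger than that of either microRNA array, and no detection filter was simulated.

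Named genes followed a rule fixed before the data were examined, as were the comparisons, the 26 gene lists and the other settings named below. The rule took CKB; the 8 genes furthest lower and the 8 furthest higher by at least 2-fold among those detected on both arrays; the 3 largest bounds in each direction among genes with a detection p of at least 0.05 on the dim array; the 8 genes furthest lower and furthest higher with both microRNAs; and at most 4 members per list at 2-fold, or 2 bright members where there were none. The lists were creatine and phosphocreatine metabolism, glycolysis, hypoxia-inducible genes, oxidative phosphorylation, cell cycle, epithelial junctions, mesenchymal genes, WNT targets and stem cell genes, goblet and secretory genes, enterocyte genes, enteroendocrine genes, interferon-stimulated genes, NF-kB targets, amino acid and unfolded protein stress, p53 targets, heat shock, cholesterol synthesis, immediate early genes, adhesion and protease genes, microRNA machinery, microRNA host genes, ribosomal proteins, metallothioneins, and markers of hepatocytes, fibroblasts, and immune and endothelial cells.

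The steps were tested on simulated arrays in which 200 genes differed between the simulated miR-483 and control arrays. The outcome depended on the noise assumed. The model first tried drew the whole background spread anew for every array; because it called many unchanged genes, a second model was then added in which part of that spread belongs to the probe and repeats on every array and undetected probes carry no signal, and both are given. With the repeating background, 100% of 4-fold and 91% of 2.5-fold genes were recovered among 11086 genes for miR-483 over control, and 12 unchanged genes passed 2-fold there, 14 of 11073 for miR-551a and 11 of 11086 for LvM3b over Ls-Parental. With independent background, 99% and 87% were recovered among 12613 genes, and 91, 70 of 12451 and 112 of 12659 unchanged genes passed. The simulated comparisons hold more genes than the observed ones, so the numbers are not directly comparable, and the data given here do not decide between the models for a single pair of arrays.

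Alternatives were no background correction, an offset of 50, median scaling, quantile normalization of the LvM3b arrays alone, the authors' scaled values, detection at 0.05, detection on both arrays, no detection filter, the mean of all probes and a 1.5-fold threshold. Leaving out replicates was not possible. The planned search for microRNA seed matches was not run, because transcript sequences were not used here. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.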

Results

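Messenger RNA levels were measured on Illumina bead arrays in 4 cultures of human colon cancer cells, with 1 array per culture. LvM3b, in 3 of the cultures, is a colon adenocarcinoma line known from published work as a derivative selected for growth in the liver. These were a control culture, a culture over-expressing the microRNA miR-483 (miR-483-5p in the series title), and a culture over-expressing miR-551a. MicroRNAs are short RNAs that lower the level or the translation of messenger RNAs carrying matching sites. The last culture was labelled Ls-Parental, a parental colon cancer line; its title and source name say so, while its cell line entry reads LvM3b. Each array carried 48803 probes, and 13861 of them were detected in the LvM3b control, 14556 with miR-483, 14447 with miR-551a and 14628 in Ls-Parental. Across all probes, Pearson's r between pairs of LvM3b arrays was 0.993 to 0.994, and between each of them and Ls-Parental 0.985 to 0.986. There were no replicates, so every difference compares single arrays, the number of arrays limits the precision, and no p-value was computed. A fold below is the ratio of normalized signals. Where a gene was above background on only 1 of the 2 arrays, the difference is a lower bound, written "at least". These bounds make no allowance for measurement noise, so a small one does not by itself show a difference. Mature microRNAs were not measured, so the over-expression itself was not checked here.

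The first comparison asked which messenger RNAs were lower when LvM3b cells carried extra miR-483. CKB, the brain-type creatine kinase, which makes phosphocreatine from creatine and ATP, was 1.49-fold lower on the miR-483 array than on the control array (log2 difference -0.58), and 2 of the 500 genes nearest to it in level were as far down. CKB was reported on because published work around this series follows it, and it may have been picked from these arrays. All 7 detected members of the creatine and phosphocreatine list were lower, with a median log2 difference of -0.26, lower than all but 0.37% of 10000 random lists of genes at like levels. The mitochondrial creatine kinases CKMT1A and CKMT1B differed by -0.03 and -0.32. The list also holds CKB itself, GAMT (-0.04) and the adenylate kinases AK1 (-0.17) and AK4, whose value is the median. The creatine transporter gene SLC6A8, singled out after its value was seen, was detected on the control array and not on the miR-483 array.

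Among genes detected on both arrays, 8 were at least 2-fold lower and 1 was at least 2-fold higher with miR-483. The lower genes were CD63, a tetraspanin of late endosomes and exosomes (2.67-fold), KIF21B, a kinesin motor (2.64-fold), MORN4 (2.47-fold), COXFA4L2, a mitochondrial protein gene formerly called NDUFA4L2 (2.25-fold), TMEM154 (2.24-fold), THBS4, an extracellular thrombospondin (2.19-fold), HOXB8, a homeobox transcription factor (2.09-fold), and STK11, the kinase LKB1 (2.01-fold). The higher gene was CPNE7, 2.01-fold, and its log2 level on the control array (6.44) lay close to the lowest detected level there, 6.38. On the miR-483 array MORN4 (log2 level 6.20), KIF21B (6.33) and THBS4 (6.37) lay close to the lowest detected level, 6.15. Such folds depend on the background correction, without which 1 gene in all was at least 2-fold lower and 2 were at least 2-fold higher. A second probe of TMEM154 differed by -0.93, and the other probes of CPNE7 by 0.48 and 0.10. TRIM60 and RUSC2, above background only on the miR-483 array, were at least 4.22-fold and at least 3.39-fold higher there, and DDX49, an RNA helicase gene, was at least 1.32-fold higher. In the other direction, PER1, a circadian clock gene, was at least 1.58-fold lower, HIF3A, of the hypoxia-inducible factor family, at least 1.54-fold, and FBLN5, an elastic fibre gene, at least 1.39-fold.

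Most genes of the amino acid and unfolded protein stress list were lower on the miR-483 array. Of the 15 detected, 13 were lower and 2 higher, none by 2-fold, and the median of -0.33 was below all 10000 random lists. ATF4, the transcription factor of the amino acid response, differed by -0.33 and PHGDH, an enzyme of serine synthesis, by -0.40. ATF3 differed by -0.53 and DDIT4, an inhibitor of mTOR signalling, by -0.64. The 4 members HSPA5, XBP1, DNAJB9 and SDF2L1, set apart after the values were seen, had a median of -0.01. Heat shock genes lay on the other side, with 8 of 10 higher and a median of 0.18, above 99.98% of random lists (HSPA1B 0.54, HSP90AA1 0.17, HSPD1 -0.07). HSPA1B was picked after its value was seen. The lists of enterocyte genes (-0.22, percentile 0.12; LGALS4 -0.23, CEACAM6 -0.45), hypoxia-inducible genes (-0.13, percentile 2.23; DDIT4 and BNIP3, -0.14) and metallothioneins (-0.10, percentile 2.33; MT1G -0.10, MT1E -0.17) were on the low side. Medians of the other lists lay within the central 95% of random lists. They were 0.06 for glycolysis, 0.01 for oxidative phosphorylation, 0.07 for the cell cycle, 0.02 for epithelial junctions, 0.03 for mesenchymal genes, 0.06 for WNT targets and intestinal stem cell genes, -0.01 for goblet and secretory genes, 0.05 for interferon-stimulated genes and -0.13 for NF-kB targets. They were 0.01 for p53 targets, 0.11 for cholesterol synthesis, 0.08 for immediate early genes, -0.02 for adhesion and protease genes, 0.07 for the microRNA machinery and 0.02 for ribosomal proteins. Fibroblast markers had a median of -0.04, and immune and endothelial markers 0.16.

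In all, 9673 genes were detected on at least 1 of the miR-483 and control arrays, and 30 were at least 2-fold lower and 32 at least 2-fold higher. Most of these lay near background. With the bound in place of the measured difference, 11 were lower and 3 higher. With the authors' own scaled values 1 was lower and 2 were higher. On the dimmer array, 22 of the 30 lower and 31 of the 32 higher genes were below background. The lowest detected log2 level was 6.38 on the control array and 6.15 on the miR-483 array, which can remove more of the higher genes. A surplus of lower genes by bound or by detection on both arrays therefore cannot be read as repression. On simulated arrays, 12 of 11086 or 91 of 12613 genes passed 2-fold in this comparison without having been changed, depending on the background noise assumed, so the count by itself does not show an effect of miR-483.

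**Figure D1:**
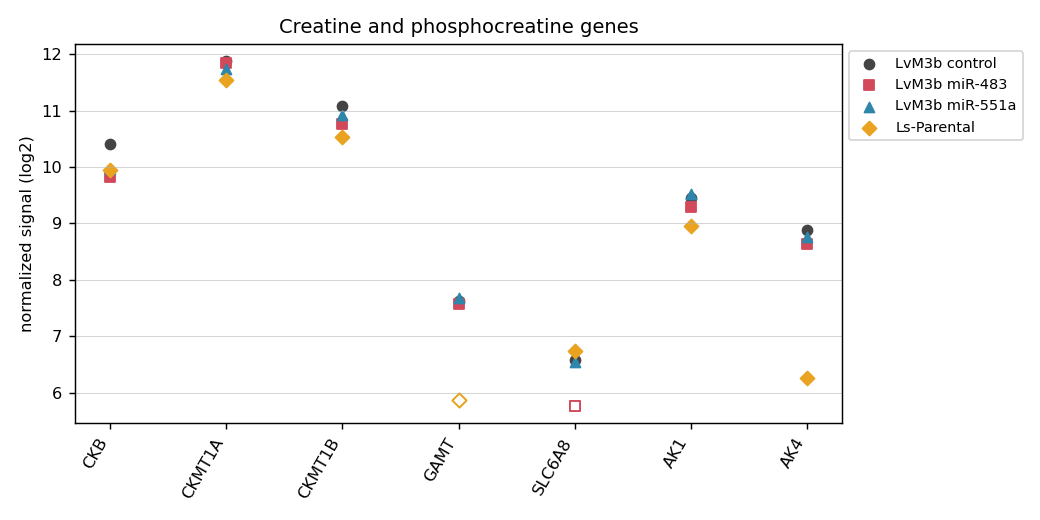
Normalized log2 signal (vertical axis) of each detected gene of the creatine and phosphocreatine list (horizontal axis) on the 4 arrays, 1 point per array, with open symbols for genes not detected on that array. CKB stands highest on the LvM3b control array, 1.49-fold above miR-483, 1.36-fold above miR-551a and 1.37-fold above Ls-Parental.

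The second comparison asked the same of miR-551a. CKB was 1.36-fold lower on the miR-551a array than on the control array (-0.45), and 11 of the 500 genes nearest in level were as far down. The gene with the largest difference measured on both arrays was DDIT4, 3.66-fold lower. TSC22D3, the glucocorticoid-induced leucine zipper, was 2.99-fold lower, and its second probe differed by -1.97. COXFA4L2 was 2.97-fold lower, SLC6A9, a glycine transporter, 2.73-fold, ATF3, a stress-induced transcription factor, 2.67-fold, ZFP1 2.38-fold, KIF21B 2.37-fold and PYROXD1 2.36-fold. The second probe of ZFP1 differed by only -0.08. On the miR-551a array PYROXD1 (log2 level 6.36), COXFA4L2 (6.43) and KIF21B (6.48) lay close to the lowest detected level, 6.19. Without background correction 6 genes in all were at least 2-fold lower and 0 were at least 2-fold higher. CHAC1, a glutathione-degrading enzyme induced by ATF4, was at least 2.18-fold lower, CBARP at least 2.20-fold and PER1 at least 1.54-fold. Higher with miR-551a were KANK2, an actin regulator (2.49-fold), and TNIP2, an inhibitor of NF-kB signalling (2.08-fold), and by bounds MAGEA11 (at least 1.30-fold), YJU2 (at least 1.21-fold) and ZNF57 (at least 1.13-fold). On the control array KANK2 (log2 level 6.43) and TNIP2 (6.59) lay close to the lowest detected level there, 6.38.

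Most genes of the stress list were again lower, 12 of 15 detected members, and 3 of them, ATF3, CHAC1 and DDIT4, at least 2-fold. The list's median was -0.57, below all 10000 random lists. The 4 members HSPA5, XBP1, DNAJB9 and SDF2L1, set apart after the values were seen, had a median of 0.15. Heat shock genes were higher (9 of 10, median 0.34, above all random lists; HSP90AA1 0.19, HSPD1 0.04). All 7 metallothioneins, which bind zinc and copper, were lower (median -0.23, percentile 0.02; MT1E -0.23, MT1G -0.16). Goblet and secretory genes (median -0.18, percentile 0.66; TFF3 -0.25, REG4 0.00) and hypoxia-inducible genes (-0.15, percentile 2.47) were on the low side. Cell cycle genes (0.11, percentile 99.04; PCNA 0.06) and cholesterol synthesis genes (0.17, percentile 99.23; INSIG1 0.19, HMGCS1 0.15) were on the high side. The creatine list, with 5 of 7 detected members lower, had a median of -0.12 at percentile 12.4, inside the central 95%.

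Within the central 95% were also glycolysis (-0.02), oxidative phosphorylation (0.05), epithelial junctions (-0.06), mesenchymal genes (0.11), WNT targets and stem cell genes (0.02), enterocyte genes (-0.13), interferon-stimulated genes (-0.06) and NF-kB targets (-0.02). So were p53 targets (0.05), immediate early genes (0.02), adhesion and protease genes (-0.08), the microRNA machinery (0.17), ribosomal proteins (-0.01), fibroblast markers (0.00) and immune and endothelial markers (0.11). Of 9619 genes detected on at least 1 of these arrays, 35 were at least 2-fold lower and 21 at least 2-fold higher. With bounds the counts were 18 and 2, with the authors' scaled values 8 and 0, and among genes detected on both arrays 14 and 2. On the dimmer array, 21 of the 35 lower and 19 of the 21 higher genes were below background. The control array's higher detection limit thus affects these counts too. On simulated arrays with no difference here, 14 of 11073 or 70 of 12451 genes passed, depending on the noise assumed.

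**Figure D2:**
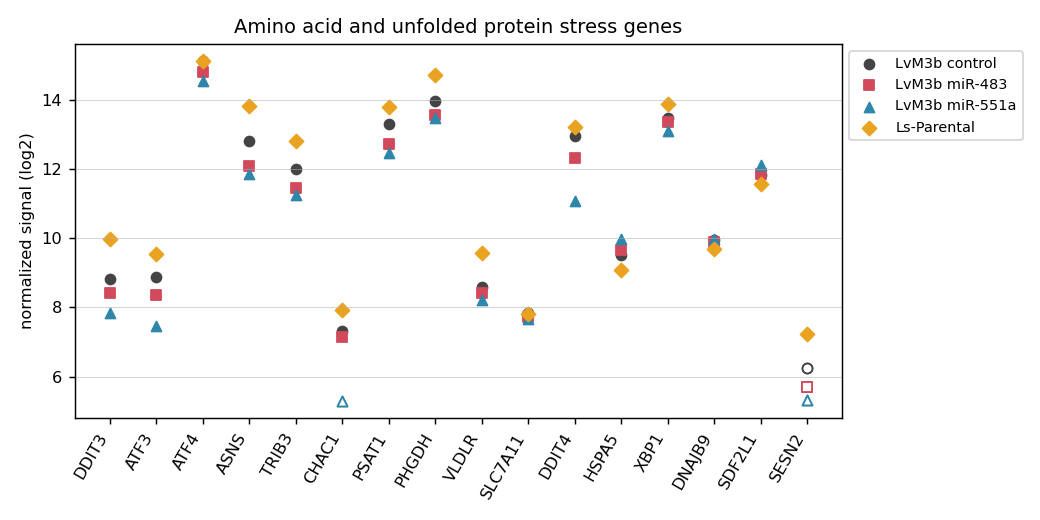
Normalized log2 signal (vertical axis) of the detected genes of the amino acid and unfolded protein stress list (horizontal axis) on the 4 arrays, 1 point per array, with open symbols for genes not detected on that array. DDIT4 stands 3.66-fold lower and ATF3 2.67-fold lower with miR-551a than in the LvM3b control.

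The third comparison asked which genes were lower or higher with both microRNAs. Across the 9482 genes detected in both comparisons, the 2 sets of log2 differences had a Pearson's r of 0.67 and a Spearman's rho of 0.63, and 73.2% of genes differed in the same direction; genes are not independent replicates. CBARP was at least 2.26-fold lower with miR-483 and at least 2.20-fold with miR-551a. KIF21B, COXFA4L2 and THBS4 were at least 2-fold lower with both and detected on all 3 LvM3b arrays. Without background correction, 0 genes were at least 2-fold lower with both. CBS, the first enzyme of transsulfuration, was at least 2.54-fold lower with miR-483 and 2.29-fold lower with miR-551a. PER1, INHBE, ZNF100, ERAP1, TLE6, DIPK2B and TMEM207 completed the 12 genes lower by 2-fold in measured value, with bounds of 1.28-fold to 1.72-fold for those of them that the naming rule covers. NOL9, TLE1, DDX49, GMPR and C10orf12 were the 5 higher with both, all below background on the control array, with bounds up to 1.56-fold.

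Both comparisons used the same control array, which alone makes them alike. Simulated arrays with no effect and a shared control gave an r of 0.45 and a covariance of 0.029 against 0.043 observed. They held on average 3.02 genes lower with both (at most 9) and 3.13 higher with both (at most 10). The simulated r was set by the control noise assumed, which was no larger than that of either microRNA array. A noisier control array would give a higher r with no effect. The simulation applied no detection filter. A gene not detected on the control array entered the observed set only if both microRNA arrays detected it. The simulated and observed counts are therefore not directly comparable. Of the 9482 genes, 30 were at least 2-fold lower with miR-483 and 35 with miR-551a, and 13 and 9 were higher. Independent lists of these sizes would share 0.11 lower and 0.012 higher genes. The joint detection rule can itself favour overlap among the higher genes. With no array in common, miR-483 over control against miR-551a over Ls-Parental gave an r of 0.16, and miR-551a over control against miR-483 over Ls-Parental 0.23. Part or all of the resemblance may come from the shared control, which could not be split off.

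**Figure D3:**
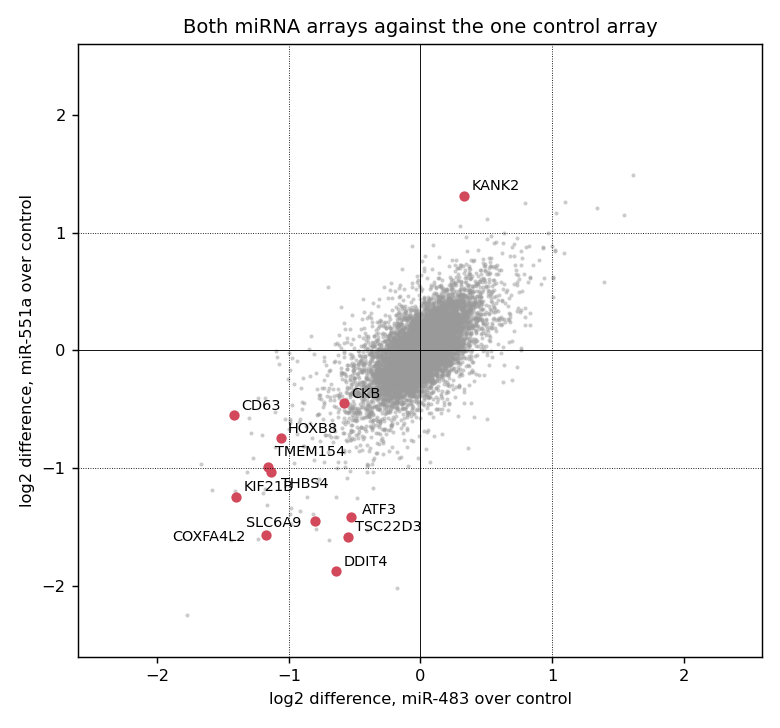
Log2 difference with miR-483 (horizontal axis) against log2 difference with miR-551a (vertical axis), both over the same LvM3b control array, with 1 point per detected gene and dotted lines at 2-fold. Points lie along the diagonal (r 0.67), DDIT4 stands lowest among the genes detected on all 3 arrays along the vertical axis, and CKB is marked at -0.58 and -0.45.

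The last comparison set the LvM3b control against Ls-Parental and gave the widest differences. SBSPON was 36.3-fold higher in LvM3b, PLAC8 32.3-fold, NRCAM, a neuronal cell adhesion molecule, 20.2-fold, and H19, an imprinted long non-coding RNA, 16.1-fold. PRR5L, a gene of the mTORC2 complex, was 15.6-fold higher, ASB4 10.2-fold, CDH11, a mesenchymal cadherin, 8.49-fold and HOXB5 8.34-fold. PPP2R2C was at least 4.33-fold higher, ROR2, a WNT5A receptor, at least 3.12-fold and the long non-coding RNA MIAT at least 2.97-fold. Lower in LvM3b were FOSB, an immediate early transcription factor (21.6-fold), BEX3 (19.7-fold), OLFM4, a marker of intestinal stem cells (9.28-fold), RHOBTB3 (8.66-fold), the Paneth cell defensins DEFA5 (8.29-fold) and DEFA6 (5.79-fold), the trypsinogen PRSS1 (8.18-fold) and NIBAN1 (6.93-fold). BEX2 was at least 14.3-fold, REG1A, a secreted lectin, at least 14.0-fold and FSTL5 at least 7.27-fold lower. Second probes of PLAC8 (5.33), NRCAM (4.59) and OLFM4 (-3.94) differed in the same directions. CKB was 1.37-fold higher on the LvM3b control array (0.45), with 46 of the 500 genes nearest in level as far up, but the miR-483 and miR-551a arrays of the same line differed from Ls-Parental by -0.12 and 0.01.

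Goblet and secretory genes were lower in LvM3b. Of 15 detected, 6 were at least 2-fold lower by measure or bound (MUC2, TFF1, TFF3, SPDEF, FCGBP and ZG16) and REG4 was at least 2-fold higher. ATOH1 and CLCA1, below background in the LvM3b control, were too dim on Ls-Parental to show 2-fold. Their median was -1.36, or -0.82 with members below background at their bounds, and the measured median lay below all random lists. The gel-forming mucin MUC2 was 3.06-fold lower, the trefoil factor TFF3 3.68-fold, the secretory transcription factor SPDEF at least 3.05-fold and the lectin ZG16 at least 2.45-fold. Some markers of white blood cells differed the same way: CD14 was at least 4.26-fold and LYZ, lysozyme, which Paneth cells also make, 5.78-fold lower in LvM3b, and the 4 detected immune and endothelial markers had a median of -1.54 (-1.33 with bounds), below all random lists. PTPRC and HLA-DRA were not detected on any array. SERPINA1, a liver protein gene, was 2.79-fold lower, while FGG was above background only on the Ls-Parental array and too near the detection limit to give a bound; the 3 hepatocyte markers detected had a median below most random lists (median -1.42, percentile 0.88, but -0.28 with bounds). The fibroblast marker genes LUM and COL3A1 were at least 4.97-fold and at least 1.41-fold higher, in a list of 5 detected with a median of 0.32 (percentile 93.75).

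Metallothioneins were lower in all 7 cases, 5 by at least 2-fold, with a median of -1.19; MT1M was 5.18-fold lower, MT1H 3.31-fold, MT1F 3.29-fold and MT1X 2.28-fold. Amino acid stress genes had a median of -0.55, with 11 of 16 lower and DDIT3 (2.22-fold) and ASNS, asparagine synthetase (2.01-fold), past 2-fold. Both lists lay below all random lists. Ribosomal protein genes had a median of -0.20 at percentile 0.19 (RPL3 -0.19, RPS6 0.06). Cholesterol synthesis genes were higher in 9 of 10 cases (median 0.80, above all random lists), with HMGCS1, the HMG-CoA synthase, 3.92-fold, SQLE 2.12-fold and INSIG1 2.08-fold higher. All 10 detected heat shock genes were higher (0.39, percentile 99.99). The creatine list was higher in 6 of 7 cases (0.51, percentile 99.9), with the adenylate kinase AK4 6.16-fold and GAMT, which makes creatine, at least 2.81-fold higher. Glycolysis (0.17, percentile 98.44; LDHA 0.60), hypoxia-inducible genes (0.22, percentile 98.07; ANKRD37 2.47-fold, EGLN3 at least 1.71-fold) and NF-kB targets (0.25, percentile 97.84; CCL20 2.17-fold higher, LCN2 2.26-fold lower) were on the high side.

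Immediate early genes at least 2-fold lower were FOSB, FOS (4.74-fold), JUN (4.55-fold) and EGR1 (3.05-fold), though the list's median was -0.04. Within the central 95% were also WNT targets and stem cell genes (-0.07; LGR5 2.06-fold and NKD1 2.05-fold higher), enterocyte genes (0.07; CEACAM6 2.62-fold higher, CA2 2.54-fold and KRT20 at least 1.26-fold lower) and interferon-stimulated genes (-0.18; BST2 at least 3.95-fold and MX1 2.07-fold higher). So were p53 targets (-0.15; GDF15 2.55-fold lower), adhesion and protease genes (-0.02; ITGB4, an integrin of hemidesmosomes, at least 5.34-fold lower, PLAU at least 1.41-fold higher), oxidative phosphorylation (0.10), the cell cycle (-0.08), epithelial junctions (-0.05), mesenchymal genes (-0.05) and the microRNA machinery (-0.02).

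Of 9817 genes detected on at least 1 of these arrays, 269 were at least 2-fold lower and 301 at least 2-fold higher in LvM3b; with bounds the counts were 176 and 237, and with the authors' scaled values 98 and 184. By measure or bound, 143 of the 176 and 168 of the 237 were also past 2-fold in the same direction when each of the miR-483 and miR-551a arrays was set against Ls-Parental, a check chosen after seeing the data that shares the single Ls-Parental array. Over genes with a second detected probe, the probes' differences correlated with r 0.74, against 0.21 for miR-483 and 0.30 for miR-551a. Over the 3 comparisons, 25 of 70 list medians lay outside the central 95% of random lists, where 3.5 would for independent lists of random genes. List members can vary together, some lists share members, and the comparisons share arrays. The 3.5 is therefore no measure of how far unchanged cultures would differ. Enteroendocrine genes were detected in 2 cases here (SCG2 and INSM1) and in 0 with either microRNA, hepatocyte markers in 2 cases with each microRNA, and of the genes hosting the microRNAs IGF2 was not detected and MEGF6 had no probe.

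**Figure D4:**
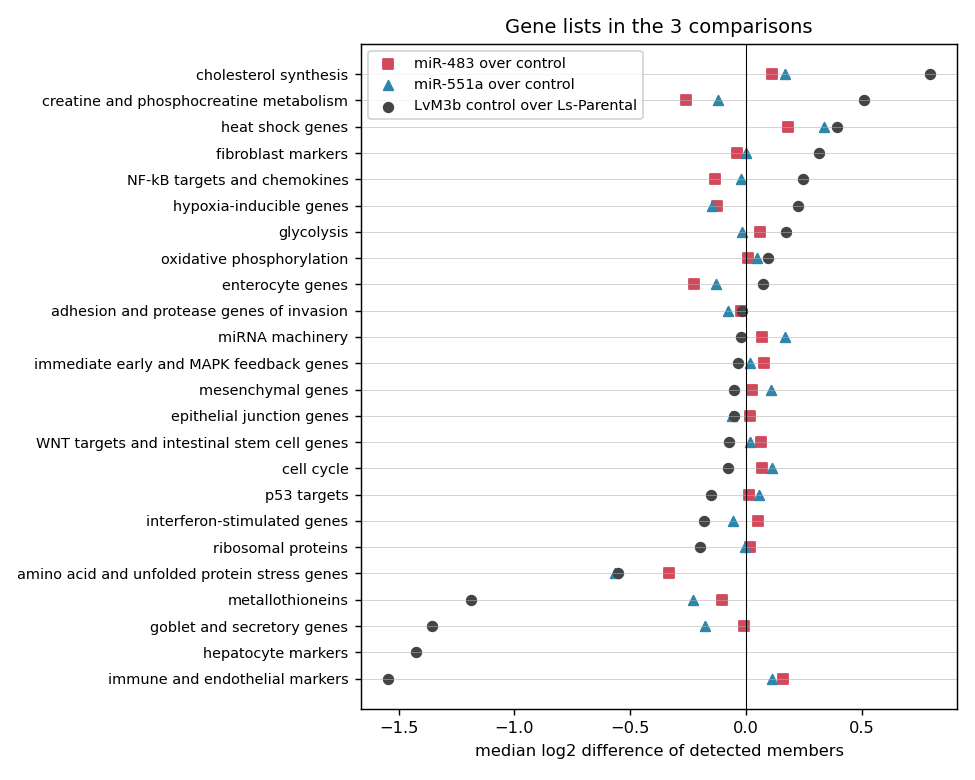
Median log2 difference (horizontal axis) of the detected members of each gene list (vertical axis, ordered by the last comparison), with 1 symbol per comparison. The stress genes lie left of 0 in all 3 comparisons (-0.33, -0.57 and -0.55), and the largest medians belong to LvM3b control over Ls-Parental.

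**Figure D5:**
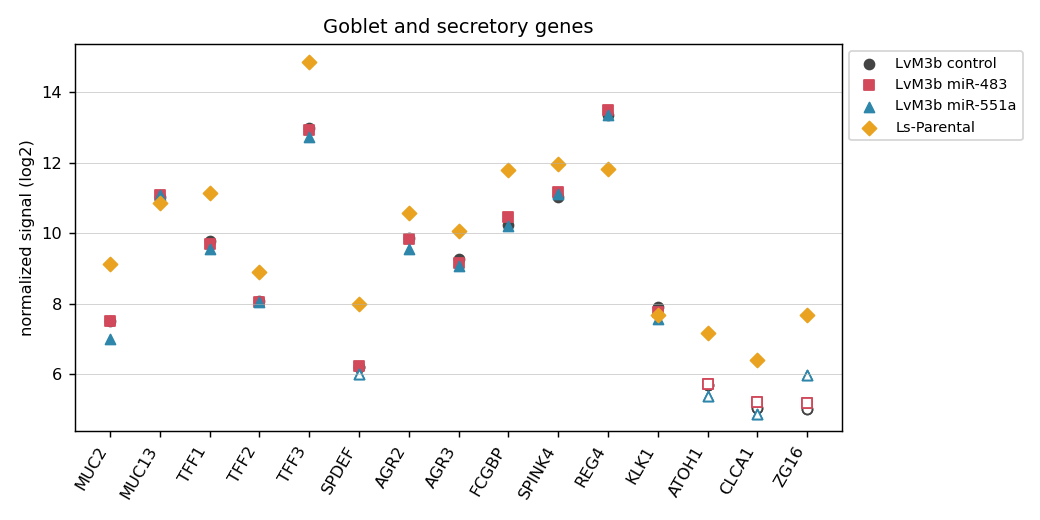
Normalized log2 signal (vertical axis) of the detected goblet and secretory genes (horizontal axis) on the 4 arrays, 1 point per array, with open symbols for genes not detected on that array. Most genes stand highest on the Ls-Parental array, TFF3 by 3.68-fold over the LvM3b control, and REG4 stands lowest there.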

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

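The tests on the common shift of the microRNA arrays by normalization, by spot noise as a part and by the control culture, those on the stress genes by random lists, scaling and control culture, and all on the secretory genes were chosen after their results were seen; the between-probe tests were set before.

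Probes that name no single gene also carried differences, which the gene counts leave out. Of 2282 such probes detected for miR-483 over control, 10 measured at least 2-fold lower and 16 higher. For miR-551a over control, 12 measured lower and 14 higher, and for LvM3b control over Ls-Parental 80 lower and 76 higher. Most were near background: by measure or bound, the counts were 1 and 0, 2 and 0, and 32 and 43.

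The microRNA comparisons resemble each other across genes (r 0.67). Spot noise of the control array as the whole cause is argued against, because the covariance between different probes of 1 gene was 0.013 (95% bootstrap interval 0.010 to 0.017 over 2299 genes), and quantile normalization is too, because r was 0.66 with the authors' single factors. Spot noise may still be the larger part, since the between-probe covariance was 29.5% of that on the same probe, though probes of a gene can also read different transcripts. Comparisons that share no array kept a covariance of 0.021 (0.017 to 0.024), but a control culture that deviates toward Ls-Parental would give this as well. These data cannot tell such a control culture apart from an effect common to both microRNAs. Nor can they tell it apart from any other handling that both microRNA cultures shared and the control did not. The control's title does not say whether it was otherwise handled like them.

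Amino acid stress genes were lower on both microRNA arrays. Independent spot noise is argued against by the random lists, 0 of 10000 of which had a median as low for either microRNA, and scaling by the list's highest median over the scalings with miR-483, -0.28. Only 4 other probes of members were detected, fewer than the 5 the planned test required. All were lower with both, with medians of -0.26 and -0.44. They belonged to ATF4, XBP1 and ASNS only and varied in size, from -0.20 to -1.99 with miR-483 and from -0.04 to -0.57 with miR-551a. A more stressed control culture cannot be told apart from an effect of the microRNAs, since the only other control, Ls-Parental, is another line and stood higher still (the list's median in LvM3b control over Ls-Parental was -0.55). An effect of the microRNAs, or of other handling that their cultures shared and the control did not, stays open and untested.

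Secretory lineage genes were lower in the LvM3b control than in Ls-Parental. A fault of the LvM3b control array is argued against, because 6 of the 6 genes past 2-fold by measure or bound were also past it on both other LvM3b arrays, and the median of the 15 detected members with bounds was -0.92 and -0.99 on those against -0.82. Markers of white blood cells are a separate matter: CD14, LYZ, CD68 and CD74 were higher in Ls-Parental than in the LvM3b control. For these markers, white blood cells mixed into the Ls-Parental sample are argued against. The lower detection p of HLA-DRA and PTPRC, abundant in such cells, was 0.515 on the Ls-Parental array. Of 20 transcripts abundant in white blood cells, these 2 among them, 18 were not detected there and 0 were at least 2-fold higher than in the LvM3b control. For the secretory genes and these markers, a difference between the lines, or of the single Ls-Parental culture or array, stays open and was not tested.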

How the results depend on the processing

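Counts at 2-fold rest on genes near background and on how background is treated, while the directions of named genes at 2-fold and the resemblance of the microRNA comparisons stayed. Of 222 named gene values, 32 turned sign under at least 1 alternative, the largest of them 0.18 in size on the log2 scale. Of those 32, 0 were among the 111 of at least 2-fold. The alternatives rework the same signals, so a difference of 2-fold could hardly change sign. Without background correction 53 of the 222 values were classed as weaker, and with the authors' values also 53. Of 70 list medians, 23 turned sign under at least 1 alternative, and 0 of these were among the 25 outside the central 95%. The r between the microRNA comparisons was 0.58 to 0.67. In LvM3b over Ls-Parental the median of all detected genes shifted from -0.01 to 0.10 with median scaling and with the authors' values, so list medians there are read relative to it. With members at their bounds, 4 list medians moved by over 0.1 and 1 turned sign. Counts follow as lower and higher for miR-483, miR-551a and LvM3b over Ls-Parental, then with both microRNAs; only counts over 1.5 times from the main value are given, and the causes were not tested unless stated.

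Without background correction they were 1 and 2, 6 and 0, 124 and 147, then 0 and 0. With the authors' scaled values they were 1 and 2, 8 and 0, 98 and 184, then 0 and 0. With an offset of 50 they were 8 and 3, 15 and 2, 177 lower, then 1 and 0. These settings compress differences of dim genes by construction. The authors' values also use a single factor per array in place of quantile normalization, and the parts of these changes were not separated. With detection on both arrays they were 8 and 1, 14 and 2, 135 and 180, then 3 and 0, since fewer genes enter. With detection at 0.05, and equally with no filter, lower counts were 63 for miR-483, 85 for miR-551a and 31 with both. The mean of all probes gave 18 and 19 lower for miR-483 and miR-551a. At 1.5-fold they were 153 and 164, 210 and 195, 743 and 711, then 67 and 42, since more genes pass. With bounds, an alternative added after seeing the data, they were 11 and 3, 18 and 2, and 176 lower. Median scaling and normalizing the LvM3b arrays alone moved no count by over 1.5 times. With the miR-483 or miR-551a array in place of the LvM3b control, also added later, 298 and 315 or 365 and 322 genes differed from Ls-Parental.

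No paired analysis was possible because each group has 1 array. Seed matches and bead errors were not run, and leaving out arrays was not possible. Signal over background limits the rest: the lowest detected signal was 178.2 on the LvM3b control array, the highest of the 4.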

Other observations

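The groups below were picked after browsing 17 gene families, so their values describe what was seen and are not tests; the test on neighbouring genes was also chosen after its result was seen. Paneth cell genes, which make antimicrobial peptides at the base of intestinal crypts, were lower in the LvM3b control than in Ls-Parental: of 9 detected, 5 were at least 2-fold lower by measure or bound (DEFA5, DEFA6, LYZ, REG1A and PLA2G2A), with a median of -1.48 with bounds. REG3A was at least 1.52-fold lower and NOD2 at least 1.30-fold higher. On the miR-483 array DEFA5 and DEFA6 stood 1.69-fold and 1.60-fold above the LvM3b control, and on the miR-551a array they differed by 0.00 and 0.24 on the log2 scale. Of 8 detected BEX and TCEAL genes, a cluster of small X-linked proteins, 3 were at least 2-fold lower in LvM3b by measure or bound (BEX2, BEX3 and TCEAL9), and the list's median with bounds was -0.23.

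Of 10 HOXB genes on the arrays, 4 were detected in LvM3b control or Ls-Parental. HOXB5, HOXB7 and HOXB8 were at least 2-fold higher on the LvM3b control array than on Ls-Parental, with log2 differences of 3.06 and 2.33 for HOXB5 and HOXB7, HOXB8 at least 13.0-fold higher, and each was lower on the microRNA arrays than on the control (-0.53, -0.35 and -1.06 with miR-483, -0.48, -0.23 and -0.74 with miR-551a). All of these differences use the control array, where a high reading would raise those over Ls-Parental and lower those with the microRNAs. The other detected gene, HOXB1, was near background on Ls-Parental and below it in the LvM3b control, with no bound. HOXB6, detected on the miR-551a array alone, was at least 1.54-fold higher there than in the control. Cancer-testis genes split: GAGE4 and GAGE7 measured -2.42 and -2.31 in LvM3b over Ls-Parental, MAGEA3 measured 1.36, and MAGEA2 was at least 2.85-fold higher.

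Within the stress list, the genes of the amino acid response were set apart from the other members, a division made after the values were seen. The 11 detected amino acid response genes had medians of -0.41 with miR-483 and -0.86 with miR-551a, and the 4 others (HSPA5, XBP1, DNAJB9 and SDF2L1) had medians of -0.01 and 0.15. The others did not go 1 way: with miR-551a the chaperone gene HSPA5 stood 1.38-fold higher and the transcription factor gene XBP1 1.30-fold lower.

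Regional copy number was examined as a hypothesis for differences between the lines. Over 9813 detected genes ordered by the GRCh38.p14 annotation, the most extreme median over 20 neighbours was 0.34 in size, within the range of 100 shuffles of the genes (0.30 to 0.51), and chromosome medians ran from -0.06 to 0.05. No stretch of 20 neighbours stood out. Smaller regions were not examined, so copy number differences are neither shown nor excluded.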
